A study of Mus musculus with 4 samples.

How the data were processed

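The deposited values came from RNA of thioglycolate-elicited peritoneal macrophages of wildtype C57BL/6 mice, harvested 3 days after injection of 2 ml of 3% thioglycolate medium, per the labels' protocols. Cells were pre-treated with MB-3 at 50 µM or with DMSO and stimulated with LPS at 100 ng/ml for 4 hours. The series title names bone marrow-derived macrophages, while the protocol and label of every sample name peritoneal macrophages, and the sample labels are followed here. RNA enriched with oligo(dT) beads went into strand-specific TruSeq libraries that were sequenced on a NovaSeq instrument, per the labels' protocols. The 4 samples form 2 groups of 2 by their titles.

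A single deposited table gave 34745 genes with Ensembl identifiers, symbols, coordinates and, for each library, a count and an FPKM value (fragments scaled to gene length and library total). The authors' counts are whole numbers per gene and not normalized, per the file headers and their values. The deposited FPKM values equal the counts divided by the library total and a gene length: the length implied by the count and FPKM pairs of a gene agreed within 0.1% in 100% of the pairs. FPKM is therefore a rescaling of the same counts with no composition factor, not an independent measurement. The submitters' processing notes name HISAT2, StringTie 1.3.0 and edgeR and the builds mm10 and GRCm38.p4. How reads that map to several genes were counted, whether counting used strand, and which annotation release was used are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes are uncertain. Columns were matched to samples by group initial and replicate number, and each column name fitted a single sample. Of the identifiers, 34344 were in GENCODE M21, which was used for biotype, GC content, 3' UTRs and matching the symbols of the gene lists. Gene length was the one implied by the deposited counts and FPKM values. No count was found in any library for 18037 genes, and 59 symbols belonged to more than 1 identifier.

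Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, model with group only), after filterByExpr and with TMM factors of 1.01 and 1.02 for DMSO and 0.966 and 1.00 for MB-3, in replicate order. P-values were adjusted by Benjamini-Hochberg over 11841 genes, and an adjusted p under 0.05 was called. The biological coefficient of variation was 0.126. Standard errors are the absolute log2 fold change divided by the square root of the F statistic, and CPM values are TMM-scaled. The totals of 15598531 to 21320618 counts make 1 count worth 0.0469 to 0.0641 CPM, and bounds and counting intervals cover counting error only. A group at 0 counts was given a bound from 3 counts over the group, and 1 to 10 counts an exact binomial 95% interval of the ratio. Replicate libraries were compared for repeated deposits: the chi-square statistic per degree of freedom between replicates was 13.8 for DMSO and 11.7 for MB-3, so neither pair was a copy within sampling noise.

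Gene lists (33, with 602 distinct genes tested, 11 of them in more than 1 list), the design, the alternatives and the rule for named genes were fixed before the data were examined. The lists covered inflammatory cytokines, chemokines, interferon-stimulated genes, NF-κB feedback with other NF-κB genes, NRF2 targets, inflammasome, Toll-like receptor 4 signalling, and SAGA and ATAC subunits. They also covered heat shock, ATF4 stress response, endoplasmic reticulum unfolded protein response, glycolysis and HIF-1, cholesterol synthesis, LXR targets, alternative activation and antigen presentation. The others were lysosome and autophagy, cell cycle, MYC and ribosome biogenesis, oxidative phosphorylation, p53 targets, immediate early genes, other LPS mediators, markers of cell types, and mitochondrially encoded genes. Lists with at least 5 tested genes (27) were tested with camera of limma 3.58.1 on log2 CPM (prior count 3) with a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists. Of these, 12 were called, 4 as higher and 8 as lower. With an estimated correlation 0 were called at the adjusted threshold, the smallest adjusted p being 0.265. The test fry, which asks whether a list's genes move on balance one way without setting them against other genes, called 16. Genes were named by rule: Kat2a and Kat2b; the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM, non-overlapping groups and an informative symbol; the 3 smallest p-values in each of 6 core lists; the 2 smallest in other pathway lists that were called or had at least 25% of members past the threshold; and the most abundant marker of each cell type. Of the genes that the rule gives, 1 is not reported here. Other genes named as members of a list were chosen after their values were seen.

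The procedures were tested on simulated data. With counts drawn for 11671 genes and known changes, edgeR recovered 72.4% of 98 genes changed 2-fold and 95.9% of 97 genes changed 4-fold. These were 71 and 93 true calls, beside which it called 23 unchanged genes. That is a larger share of false calls than the adjusted threshold is meant to allow. With a replicate block, 76 unchanged genes were called beside 80 and 94 true calls. No replicate effect was simulated, so this count does not judge the block for samples that are paired. Far fewer genes were changed in the simulation than were called in the data (4391). The share of false calls in the data was therefore not measured. With lists of simulated genes shifted by 0.5 on the log2 scale, camera with the preset correlation called 10 of 10 shifted and 0 of 30 unchanged lists. The estimated correlation called 0 of the 10 shifted lists, so a missed call with it carries little information for a shift of that size. Larger shifts were not simulated. The simulated genes varied independently, so the preset correlation of 0.01 was not tested on correlated genes. In the data the estimated correlation was 0.333 for interferon-stimulated genes, so camera's p-values for such lists may be too small. Alternatives were other size factors, no composition factor, no filter, a stricter filter (at least 1 CPM in every library of a group and a mean of at least 5 CPM), DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean FPKM of at least 1 or of all genes, a 2-fold minimum, a replicate block and leaving out each library. After the data were seen, a gene length and GC correction (loess offsets, span 0.5), a test of protein-coding genes alone and list tests with no composition factor were added. Where a library is left out, the lone sample of its group is assumed to vary like the other group. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 served for the permutation test and matplotlib 3.10.9 for the plots.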

Results

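RNA was sequenced from mouse peritoneal macrophages, the cells that gather in the abdominal cavity after injection of thioglycolate broth and that were then grown as adherent cells. The mice were wildtype C57BL/6. All samples had been stimulated with lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that activates Toll-like receptor 4, at 100 ng/ml for 4 hours. Before LPS, the cells had received either MB-3 at 50 µM or its solvent DMSO. MB-3 is a small molecule described as an inhibitor of the lysine acetyltransferase GCN5, which is encoded by Kat2a. There were 2 DMSO libraries and 2 MB-3 libraries, and no cells without LPS were analysed here. The total count was 21320618 and 15598531 in DMSO replicates 1 and 2, and 18538799 and 17864065 in MB-3 replicates 1 and 2. Between 14323 and 14715 genes had at least 1 count in a library. The 10 most abundant genes took 13.28% and 13.14% of the counts with DMSO and 18.99% and 19.42% with MB-3. Nothing in the labels says whether replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

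The comparison asked which transcripts of LPS-stimulated macrophages differed after pre-treatment with MB-3. Il1b, the gene of the pyrogenic cytokine interleukin-1 beta, fell from 6504 ± 471 CPM (counts scaled to library size; SD, n = 2) with DMSO to 26.5 ± 2.22 with MB-3, a 245-fold lower level. Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, went the other way, from 96.8 ± 4.34 to 12351 ± 52.6 CPM (SD, n = 2), a 128-fold rise. Edn1, the gene of the vasoconstrictor peptide endothelin-1, was at 231 ± 22.2 CPM with DMSO and had 2 counts in the 2 MB-3 libraries together, a ratio of 4170 with an exact 95% interval from 1154 to 34441 for counting error. Csf2, which encodes the growth factor GM-CSF, was at 21.4 ± 2.03 CPM with DMSO and had 0 counts with MB-3, at least 253-fold lower when 3 counts over the group are taken as the floor.

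Of 11841 genes tested, 1999 were higher and 2392 lower with MB-3 at an adjusted p of 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The groups did not overlap for 70.8% of the tested genes, against 33.3% by chance for 2 samples against 2. Log2 CPM values correlated across genes with r = 0.986 between the DMSO libraries and 0.986 between the MB-3 libraries, and with 0.922 to 0.928 between libraries of different groups. Genes are not independent replicates, so these correlations describe the libraries only. Without MB-3 replicate 1, the number of higher genes was 1283.

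**Figure D1:**
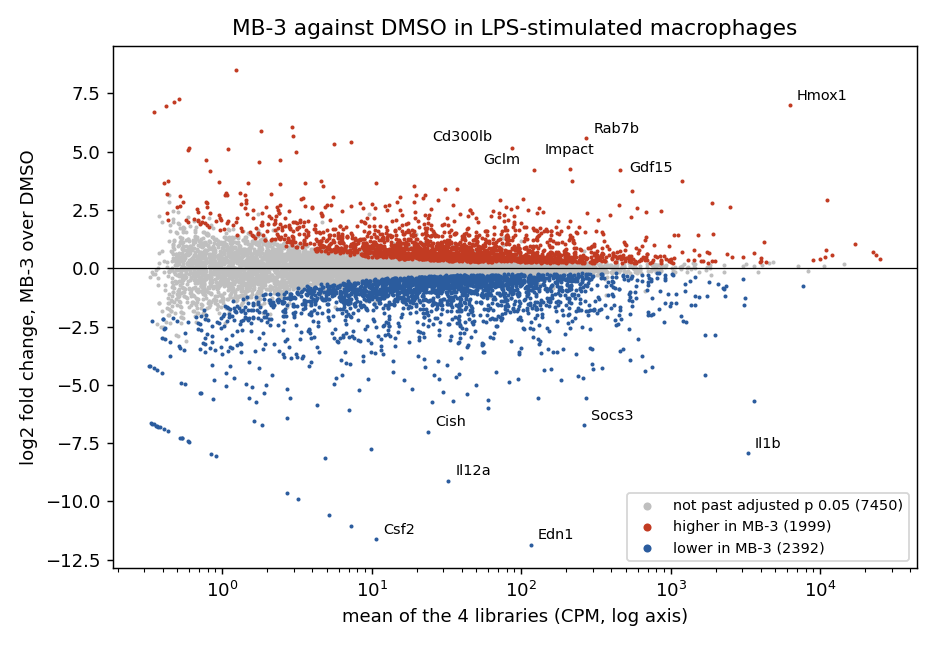
Log2 fold change of each tested gene (MB-3 over DMSO, vertical axis) against its mean level over the 4 libraries (CPM, logarithmic horizontal axis). The 1999 higher genes are red, the 2392 lower genes blue and the 7450 others grey, and the 12 labelled genes are the 6 largest rises and the 6 largest falls among well-expressed genes, with Hmox1 uppermost among them and Edn1 lowest, at -11.85.

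Among named, non-predicted genes with a mean of at least 10 CPM, the 6 largest falls were those of Edn1, Csf2, Il12a, Il1b, Cish and Socs3. Il12a, which encodes the p35 subunit of interleukin-12, had 65.0 ± 17.1 CPM with DMSO and 4 counts in the MB-3 libraries together, a ratio of 598 with an exact 95% counting interval from 233 to 2195. Both Cish and Socs3 encode feedback inhibitors of cytokine receptor signalling. Cish fell from 47.4 ± 4.60 to 0.363 ± 0.276 CPM, the latter from 3 and 10 counts, so the size of the fall is uncertain (log2 fold change -8.09 without MB-3 replicate 2). Socs3 fell by 6.72 on the log2 scale (SE 0.11), from 521 ± 33.9 to 4.94 ± 0.203 CPM. The 6 largest rises were those of Hmox1, Rab7b, Cd300lb, Impact, Gclm and Gdf15. Rab7b, the gene of a small GTPase of the endosomal system, rose from 11.2 ± 3.31 to 534 ± 2.44 CPM (log2 fold change 5.56, SE 0.20). Cd300lb, which encodes an activating myeloid receptor, rose from 4.74 ± 0.833 to 168 ± 1.05 CPM (5.16, SE 0.14). Impact, an inhibitor of the translational stress kinase GCN2, rose from 20.9 ± 4.16 to 400.3 ± 0.778 CPM (4.26, SE 0.15). Gdf15, a cytokine induced by cell stress, rose from 46.8 ± 11.2 to 866 ± 74.1 CPM (4.21, SE 0.18). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 1.24e-06 for Il1b, 9.65e-07 for Hmox1 and 4.84e-05 for Csf2. In the coordinates of the deposited table, whose notes name the builds mm10 and GRCm38.p4, Il1b (ENSMUSG00000027398) is a protein-coding gene on chromosome 2 from 129364570 to 129371139. Hmox1 (ENSMUSG00000005413) is a protein-coding gene on chromosome 8 from 75093591 to 75100596.

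The genes of the enzymes that MB-3 is described to act on had low to moderate levels. Kat2a (ENSMUSG00000020918, chromosome 11 from 100704746 to 100712465) was at 11.4 and 10.8 CPM in the DMSO libraries and at 6.59 and 11.3 CPM in the MB-3 libraries. Its log2 fold change of -0.31 (SE 0.26) did not pass the threshold, with an adjusted p of 0.397 in edgeR's quasi-likelihood test. Without MB-3 replicate 2 the log2 fold change was -0.75 and the edgeR adjusted p 0.0436, while the adjusted p ranged from 0.0436 to 0.919 over 16 alternative settings with edgeR, DESeq2 or limma. Kat2b (ENSMUSG00000000708, chromosome 17 from 53566861 to 53672720), which encodes the related acetyltransferase PCAF, fell from 47.8 ± 1.05 to 23.6 ± 0.409 CPM (log2 fold change -1.02, SE 0.092, edgeR adjusted p = 4.08e-04). The list of subunits of SAGA and ATAC, the coactivator complexes that hold these enzymes, had 31 tested genes, of which 6 were higher, 5 were lower and 20 did not pass. Adjusted over the list alone, 7 were higher and 6 lower. Atxn7l1 fell from 16.7 to 5.92 CPM, and Hcfc1, a shared chromatin cofactor, rose by 1.65 on the log2 scale (SE 0.15). As a set this list did not stand apart from other genes (limma's camera, adjusted p = 0.529).

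Inflammatory cytokine genes fell together: of 23 tested, 18 were lower and 1 was higher, with a median log2 fold change of -3.005, also with Csf2 at its bound. Adjusted over the list alone, 19 were lower and 1 higher. Il1a fell from 7076 ± 53.9 to 136 ± 7.87 CPM (log2 fold change -5.70, SE 0.083) and Il6 from 532 ± 21.7 to 11.2 ± 0.446 CPM (-5.56, SE 0.093). Tnf, near the list's median, was at 2979 CPM with DMSO and 405 CPM with MB-3 (-2.88, SE 0.13). The member that rose was Vegfa, a gene of blood vessel growth (2.14, SE 0.12), and Osm had a log2 fold change of 0.04 (SE 0.11). The set was lower than other genes (limma's camera, adjusted p = 1.82e-09), with an adjusted p of 0.265 with an estimated correlation.

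Of 21 chemokine genes, 15 were lower and 2 higher, with a median of -1.21, and the counts adjusted over the list alone were also 15 and 2. Ccl2, which attracts monocytes, fell from 3267 ± 462 to 136 ± 34.7 CPM (-4.59, SE 0.21). Cxcl10, a chemokine induced by interferon, fell from 3486 ± 124 to 486 ± 61.7 CPM (-2.84, SE 0.10), and Cxcl16 fell by 2.02 (SE 0.086). Cxcl2, which attracts neutrophils, was at 1007 CPM with DMSO and 1020 CPM with MB-3 (0.02, SE 0.093), while the related Cxcl1 fell by 1.95 (SE 0.093). Ccl6 (0.43) and Cxcl5 (2.16) rose. The chemokine list was lower than other genes (limma's camera, adjusted p = 5.37e-05, and adjusted p = 0.373 with an estimated correlation).

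**Figure D2:**
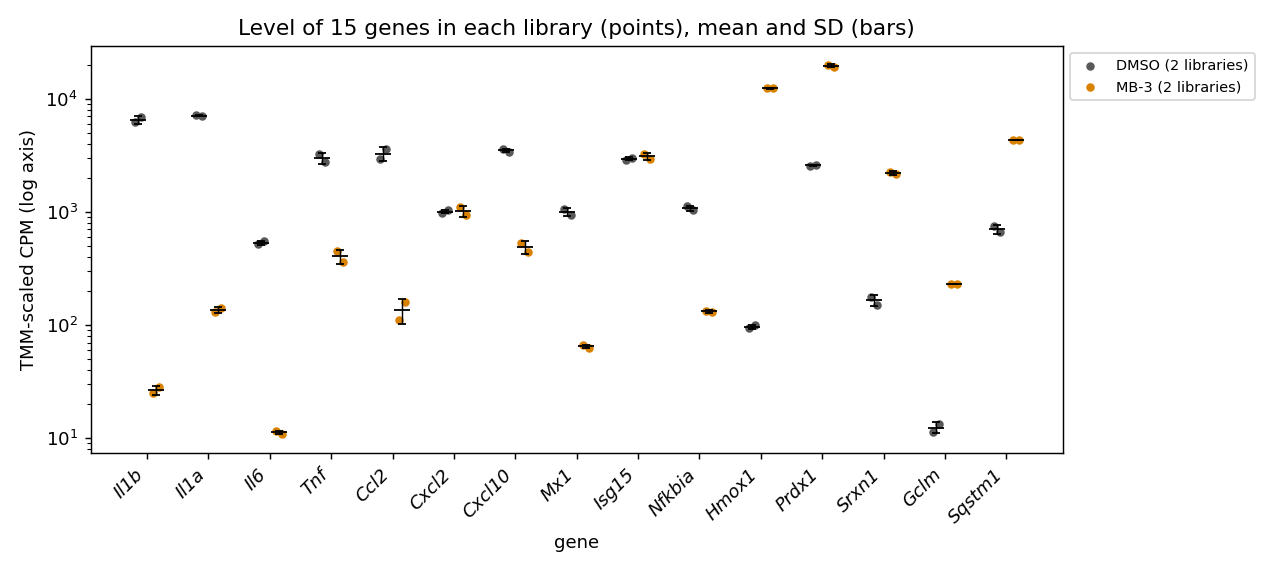
Level of 15 genes in each library (TMM-scaled CPM, logarithmic axis), with grey points for the 2 DMSO libraries, orange points for the 2 MB-3 libraries, and black bars for mean and SD. The genes were chosen after their values were seen, and they show Il1b falling from 6504 to 26.5 CPM, Hmox1 rising from 96.8 to 12351 CPM, and Cxcl2 at 1007 and 1020 CPM.

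Genes induced by interferon were lower in 38 of 42 cases, with a median of -1.58 and no member past the threshold in the other direction. Adjusted over the list alone, 38 were lower and 0 higher. Mx1, read here only as a transcript induced by interferon, fell from 995 ± 78.3 to 64.8 ± 2.36 CPM (-3.94, SE 0.092). Irf7, a transcription factor that amplifies interferon production, and Usp18, which removes ISG15 from proteins, each fell by 3.47 (SE 0.076 and 0.082). Isg15 itself was at 2942 and 3096 CPM in the DMSO and MB-3 groups (0.07, SE 0.075). This list was lower than other genes (limma's camera, adjusted p = 3.24e-15, and adjusted p = 0.399 with an estimated correlation). Members of the Ifit, Oas and Gbp families resemble each other in sequence, and their single values are uncertain where the authors' counting could have split or shared reads.

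The NF-κB feedback list also holds subunits of NF-κB, such as Rel and Rela, and other targets, such as Icam1. Its genes were lower in 22 of 27 cases and higher in 3, with a median of -1.58. Adjusted over the list alone, 23 were lower and 3 higher. Icam1, an adhesion molecule, fell from 662 ± 34.5 to 34.5 ± 1.90 CPM (-4.26, SE 0.091). Nfkbia, the gene of the inhibitor IκBα, fell from 1075 ± 62.7 to 132 ± 3.46 CPM (-3.03, SE 0.080). The members that rose were the MAP kinase phosphatase gene Dusp1 (0.86), Bcl3 (0.81) and the stress-induced repressor gene Atf3 (0.52). The list was lower than other genes (limma's camera, adjusted p = 5.35e-08, and adjusted p = 0.399 with an estimated correlation).

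Inflammasome and pyroptosis genes numbered 20, of which 14 were lower and 3 higher, and the same counts held adjusted over the list alone. Besides Il1b, Gsdmd, which encodes a pore-forming protein, fell by 1.84 (SE 0.094), Casp4, a sensor of intracellular LPS, by 1.59 (SE 0.077) and Nlrp3 by 1.52 (SE 0.23). Ninj1, which encodes a protein of plasma membrane rupture, rose by 1.59 (SE 0.12). Camera put the list below other genes (limma's camera, median -1.37, adjusted p = 4.73e-04, and adjusted p = 0.441 with an estimated correlation).

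Antigen presentation genes split within the list. The co-stimulatory receptor gene Cd40 fell from 1284 ± 25.5 to 60.2 ± 3.13 CPM (-4.42, SE 0.082), and Cd83 fell by 3.75 (SE 0.10). The immunoproteasome subunits Psmb8, Psmb9 and Psmb10 and the peptide transporters Tap1 and Tap2 fell by 1.56 to 2.57. Of 10 tested members with an H2 symbol, the genes of MHC chains and related molecules, H2-Q7 (-1.76, SE 0.24) and the barely detected H2-Oa (-3.45, SE 0.67) were lower, and the other 8 did not pass, with log2 fold changes from -0.17 to 0.35. H2 genes resemble each other in sequence, so their single values are uncertain. B2m (0.13, SE 0.24) and the invariant chain gene Cd74 (0.07, SE 0.18) did not pass. Of 25 tested, 14 were lower and 0 higher, against 14 lower and 1 higher adjusted over the list alone (limma's camera, median -1.20, adjusted p = 4.73e-04). The adjusted p was 0.483 with an estimated correlation. Over 10 alternatives in limma's camera the list was called each time, and its median ran from -1.29 to -0.41, the latter with the stricter filter.

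Other LPS-induced mediators included 16 lower and 3 higher genes of 29, against 17 and 3 adjusted over the list alone. Ptgs2, which encodes the prostaglandin enzyme cyclooxygenase-2, fell from 572 ± 27.2 to 28.4 ± 1.43 CPM (-4.33, SE 0.090), and Nos2, the inducible nitric oxide synthase gene, fell by 5.75 (SE 0.18). Among the genes that did not pass, Saa3 had a log2 fold change of -0.19, Plaur of -0.12 and Clec4e of -0.04. Those that rose were Ass1 (3.03), Thbs1 (2.29) and Plau (1.78), and Ass1 has a processed pseudogene, Gm5424, which rose by 2.92, so its value is uncertain where the counting shared reads between them. The median was -0.999 (limma's camera, adjusted p = 8.61e-05, and adjusted p = 0.399 with an estimated correlation).

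Targets of NRF2, the transcription factor of the response to electrophiles and oxidants, rose together, with 28 of 30 higher, 0 lower and a median of 1.88. Adjusted over the list alone, 28 were higher and 0 lower. Prdx1, which encodes a peroxide-reducing enzyme, rose from 2588 ± 28.9 to 19468 ± 599 CPM (2.91, SE 0.064). Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, rose from 12.4 ± 1.37 to 231 ± 2.01 CPM (4.22, SE 0.11). Srxn1, Slc7a11 and Txnrd1, which act in redox repair and cystine uptake, rose by 3.74, 2.71 and 2.43. The members that did not pass were Txn1 (0.12, SE 0.15) and Abcc4 (-0.19, SE 0.15). The list was higher than other genes (limma's camera, adjusted p = 1.42e-14, and adjusted p = 0.265 with an estimated correlation). The share of counts from mitochondrially encoded genes was also higher with MB-3, at 2.27% and 2.22% against 1.79% in each DMSO library.

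Lysosome and autophagy genes were higher in 16 of 28 cases and lower in 0, and 18 were higher adjusted over the list alone. Sqstm1, the gene of the autophagy receptor p62 and also an NRF2 target, rose from 705 ± 66.3 to 4305 ± 29.7 CPM (2.61, SE 0.085). Gabarapl1 rose by 1.47 (SE 0.068), and Tfeb, a transcription factor of lysosome genes, rose by 2.67 (SE 0.17). The median was 0.29 (limma's camera, adjusted p = 4.84e-05, and adjusted p = 0.399 with an estimated correlation).

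Heat shock genes numbered 21, of which 11 were higher and 2 lower, or 12 and 2 adjusted over the list alone. Hspa8 rose by 0.76 (SE 0.069) and Dnajb1, a co-chaperone gene, by 0.79 (SE 0.090), while the co-chaperone genes Stip1 and Hspe1 fell by 0.46 and 0.38. The median was 0.44 (limma's camera, adjusted p = 6.77e-03, and adjusted p = 0.405 with an estimated correlation).

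**Figure D3:**
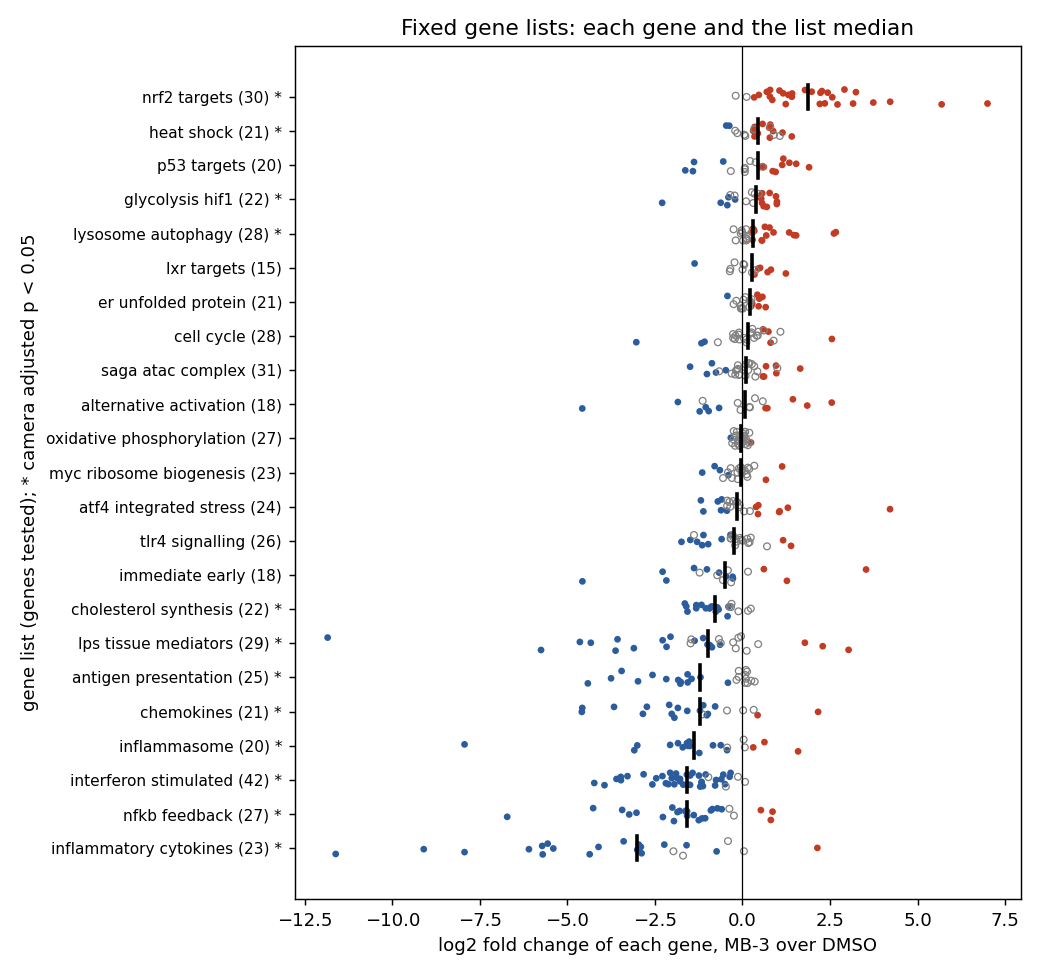
Log2 fold change (MB-3 over DMSO, horizontal axis) of every tested gene in 23 pathway lists, with the number of genes tested in brackets, the list median as a black bar and an asterisk where limma's camera called the list. Red and blue points passed edgeR's threshold and open points did not, and the medians run from 1.88 for NRF2 targets to -3.005 for inflammatory cytokines.

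Cholesterol synthesis genes were lower in 16 of 22 cases and higher in 0, with the same counts adjusted over the list alone. Sc5d, which encodes a late enzyme of the pathway, fell from 61.3 ± 3.66 to 24.6 ± 2.39 CPM (-1.32, SE 0.11). The median was -0.78 (limma's camera, adjusted p = 4.84e-05, and adjusted p = 0.399 with an estimated correlation). Of 15 LXR targets, genes switched on by oxysterols, 6 were higher and 1 was lower. Adjusted over the list alone, 6 were higher and 1 lower. Mylip, which encodes a ubiquitin ligase, rose by 1.24 (SE 0.17) and Mertk, a receptor for dying cells, fell by 1.37 (SE 0.19). The LXR list was not called (limma's camera, adjusted p = 0.161), except on log2 FPKM (adjusted p = 0.0405).

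Glycolysis and HIF-1 target genes were higher in 10 of 22 cases and lower in 5, or 12 and 5 adjusted over the list alone. Pkm, the pyruvate kinase gene, rose by 0.96 (SE 0.067), while Hk2, a hexokinase gene induced by LPS, fell by 2.29 (SE 0.14). The list was called as higher with a median of 0.38 (limma's camera, adjusted p = 0.0377, and adjusted p = 0.399 with an estimated correlation). That call was lost without DMSO replicate 2 (adjusted p = 0.125), without MB-3 replicate 1 (adjusted p = 0.0748), with the stricter filter (adjusted p = 0.0549), with a replicate block (adjusted p = 0.06395) and with a gene length and GC correction (adjusted p = 0.05885), and camera's adjusted p ranged from 0.0269 to 0.125 over 10 alternatives. Nuclear genes of oxidative phosphorylation moved little, with 1 higher, 1 lower and 25 of 27 not past the threshold, 0 and 0 adjusted over the list alone, and no call (limma's camera, adjusted p = 0.976).

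Several stress and growth lists held members that moved in both directions and were not called by limma's camera in the main analysis. Of 24 genes of the ATF4 stress response, 7 were higher and 6 lower (7 and 6 adjusted over the list alone), the adjusted p was 0.814, and the median of -0.15 and the mean of 0.09 differed in sign. Ddit3, which encodes the stress factor CHOP, rose by 1.29 (SE 0.087), and the serine synthesis gene Psat1 fell by 1.19 (SE 0.082). Of 21 endoplasmic reticulum genes of the unfolded protein response, 8 were higher and 1 lower (8 and 1 adjusted over the list alone; limma's camera, adjusted p = 0.0580). Camera called this list as higher in 2 of 10 alternatives, with DESeq2's size factors (adjusted p = 0.0492) and with the length and GC correction (adjusted p = 0.0283). Ern1, the gene of the sensor IRE1, rose by 0.66 (SE 0.10), and Dnajc3 rose by 0.57 (SE 0.085). Among 20 p53 targets, 9 were higher and 4 lower (9 and 4 adjusted over the list alone; limma's camera, adjusted p = 0.0651), with rises of 1.90 for Gadd45a and 1.13 for Mdm2 and a fall of 1.63 for Cdkn1a. Cell cycle genes gave 4 higher and 3 lower of 28 (3 and 3 adjusted over the list alone; limma's camera, adjusted p = 0.185), where Bub1b, a mitotic checkpoint gene, rose by 2.55 (SE 0.087) and Mcm6, of the replicative helicase, fell by 1.08 (SE 0.089). The joint list of MYC and ribosome biogenesis genes gave 2 higher and 4 lower of 23 (2 and 4 adjusted over the list alone). It was not called (limma's camera, adjusted p = 0.561), with falls of 1.15 for Wdr43 and 0.80 for Odc1.

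Immediate early genes gave 3 higher and 9 lower of 18 (3 and 10 adjusted over the list alone), and the list missed the threshold (limma's camera, adjusted p = 0.0580). Nr4a3, an orphan nuclear receptor gene, fell from 12.05 ± 3.39 to 0.502 ± 0.0784 CPM (-4.57, SE 0.34) and Junb, of the AP-1 family, fell by 2.28 (SE 0.078). Camera called that list as lower in 4 of 10 alternatives, with adjusted p from 0.0238 (without DMSO replicate 1) to 0.0413 (replicate block), and its largest adjusted p was 0.152. Components of Toll-like receptor 4 signalling gave 2 higher and 8 lower of 26 (2 and 9 adjusted over the list alone; limma's camera, adjusted p = 0.136). The receptor gene Tlr2 fell by 1.74 (SE 0.087) and the adaptor gene Myd88 fell from 323 to 131 CPM, while Ticam1, of the other adaptor arm, rose by 1.16 (SE 0.12). Tlr4 itself had a log2 fold change of -1.39 (SE 0.63) that did not pass, with an edgeR adjusted p of 0.135. Of 18 genes of alternative activation, 5 were higher and 6 lower (5 and 6 adjusted over the list alone; limma's camera, adjusted p = 0.942), and the median of 0.07 and the mean of -0.17 differed in sign. Pparg, a lipid-sensing nuclear receptor gene, rose by 2.55 (SE 0.11) and Il4ra, an interleukin-4 receptor gene, fell by 1.22 (SE 0.088). The test fry of limma, which sets a list against no change and not against other genes, called 4 lists that camera did not: immediate early genes (adjusted p = 0.00149), Toll-like receptor 4 signalling (adjusted p = 0.0267) and the ATF4 stress response (adjusted p = 0.0434) as lower, and alternative activation (adjusted p = 0.00558) as higher.

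Markers of cell types were low or went both ways. Among 10 macrophage markers, 4 were higher and 4 lower, also when adjusted over the list alone, with a median of 0.17 and a mean of -0.17 (limma's camera, adjusted p = 0.995). Lyz2, the most abundant of them, rose from 21843 ± 404 to 28300.3 ± 5.46 CPM (0.37, SE 0.057), while Fcgr1 fell by 2.38 (SE 0.15). Of 8 tested markers of resident peritoneal macrophages, 0 passed, and 0 adjusted over the list alone (limma's camera, adjusted p = 0.995). Their median of 0.07 differed in sign from the mean of -0.11 and ran from -0.86 to 0.62 over 8 alternatives. Cd5l was at 43.9 ± 22.5 and 68.7 ± 29.7 CPM (0.65, SE 0.41, edgeR adjusted p = 0.259). Without DMSO replicate 2 its log2 fold change was 1.31 with an edgeR adjusted p of 0.0295, within a range of 9.1e-04 to 0.848 over 16 alternatives. Of 3 neutrophil markers, 2 were lower, over all genes and adjusted over the list alone, Csf3r (40.3 ± 2.89 to 14.1 ± 3.29 CPM) and S100a8 (21.8 ± 0.247 to 10.7 ± 1.95 CPM). The T and NK cell list had 2 tested genes, Il7r, which rose from 133 ± 18.5 to 651 ± 102 CPM (2.29, SE 0.14), and Lck, which fell from 16.8 to 2.01 CPM, and both passed adjusted over the list alone. Of 3 dendritic cell markers, Ccr7 was higher (1.28), Batf3 lower (-1.88) and Zbtb46 not past the threshold (0.65, SE 0.26), and adjusted over the list alone 2 were higher and 1 lower. For B cells (4 tested, with Ighm at 2.31 and 3.38 CPM), mesothelial cells and fibroblasts (7 tested, with Dcn at 59.8 ± 28.7 and 76.0 ± 33.6 CPM, log2 fold change 0.35, and -0.19 to 0.96 over 16 alternatives), mast cells and eosinophils (Siglecf, -0.04, SE 0.21) and red cells and platelets (Pf4, 0.32, SE 0.22), 0 genes passed, and 0 adjusted over each list alone. With a replicate block, which compares same-numbered libraries, Cd5l, Dcn and Pf4 passed as higher, by 0.67, 0.36 and 0.34 (edgeR adjusted p = 9.1e-04, 0.0114 and 0.0437). In replicates 1 and 2, Cd5l was at 28.0 and 59.8 CPM with DMSO and 47.7 and 89.6 with MB-3. Dcn was at 39.5 and 80.1 CPM against 52.2 and 99.7, and Pf4 at 26.6 and 41.7 against 37.7 and 47.0. On simulated counts the block called 76 unchanged genes against 23 without it. Those counts held no replicate effect, so they do not decide these calls, and whether the samples are paired is not known. Pf4 also passed without DMSO replicate 2 (log2 fold change 0.68, edgeR adjusted p = 0.0235, range 0.0235 to 0.791 over 16 alternatives). The mesothelial and fibroblast list was not called (limma's camera, adjusted p = 0.561), and its median of 0.35 ran from -0.12 to 1.02 over 8 alternatives.

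Of 13 mitochondrially encoded genes, 5 were higher and 0 lower, with the same counts adjusted over the list alone (limma's camera, adjusted p = 0.0639). The most abundant, mt-Co1, rose from 9106 ± 575 to 12548 ± 762 CPM (0.46, SE 0.076), and mt-Nd4 rose by 0.35 (SE 0.072). Without MB-3 replicate 1 mt-Nd4 had an edgeR adjusted p of 0.0557, within a range of 4.8e-04 to 0.0557 over 16 alternatives. Camera called the list as higher in 3 of 10 alternatives, with adjusted p from 0.00691 (length and GC correction) to 0.0480 (without DMSO replicate 1), and its largest adjusted p was 0.109.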

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

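The gene length and GC correction, the protein-coding subset and the list tests with no composition factor were chosen after the result was seen. Across 16 other settings of the gene test, genes higher with MB-3 numbered 1283 to 2508 and genes lower 1726 to 2706, and 0 of the 4391 called genes became a call in the opposite direction. An opposite call was unlikely, because every setting used the same counts. Of the 4391 calls, 3836 were kept with DESeq2 and 3293 with limma on log2(FPKM + 1) of all genes. More calls were lost without either MB-3 replicate. With a minimum change of 2-fold, 623 genes were higher and 1104 lower, by construction. Leaving out 1 library gave 1283 (without MB-3 replicate 1) to 1802 higher genes, where fewer samples were fitted, and 1726 to 1936 lower genes. The share of calls that were lower was 54.5%, with 45.5% to 60.9% across settings. The balance turned with the gene length and GC correction, which gave 2508 higher and 2095 lower genes, and narrowly without DMSO replicate 1. Which direction holds more genes therefore depends on the setting. A replicate block raised the counts to 2340 higher and 2706 lower genes and called 12 lists, with glycolysis and HIF-1 targets lost and immediate early genes gained. On simulated counts without a replicate effect the block called more unchanged genes (76 against 23). Whether equal replicate numbers pair the samples is not known: deviations of same-numbered libraries correlated across genes at 0.217, and the second principal component (10.9% of variance) separated number 1 from number 2 in both groups. With an estimated correlation 0 lists were called, where 11 to 16 were called under the other settings. Of the called lists, glycolysis and HIF-1 targets alone lost the call in other settings than the estimated correlation, under 5 of 11, and the cause was not tested. Named genes kept their direction and side of the threshold in 1057 of their comparisons with another setting, gained a call in 6 and lost it in 2 (Lyz2 with unfiltered FPKM, mt-Nd4 without MB-3 replicate 1). Most named genes were picked for small p-values or large changes in these same counts, so their stability was largely set by that choice. It does not speak for the other called genes. Depth limits genes such as Ifnb1, at 0.656 and 0.195 CPM, from 12 counts in each DMSO library and 6 and 1 with MB-3.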

Other observations

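The gene family test and the genes of iron, zinc and lipid handling in this part, and the tests against library composition and RNA of other cell types, were chosen after the result was seen. Iron and haem genes were not tested as a set, and those given here were picked for their rise. Slc40a1, which encodes the iron exporter ferroportin, rose from 0.281 ± 0.13 to 10.9 ± 1.1 CPM (log2 fold change 5.31, SE 0.34, n = 2). With 1 count worth 0.0469 and 0.0641 CPM in the DMSO libraries, its DMSO level rests on few counts, so the size of the rise is uncertain. Among NRF2 targets, the haem transporter gene Slc48a1 rose by 2.21, the biliverdin reductase gene Blvrb by 1.31 and the ferritin genes Ftl1 and Fth1 by 1.06 and 0.69, and ferritin values are uncertain because processed copies of these genes exist. Plin2, a lipid droplet coat gene, rose from 472 ± 8.3 to 3296 ± 23 CPM (2.80, SE 0.065), with rises of 1.43 for the lysosomal lipase gene Lipa and 1.58 for the cholesterol esterification gene Soat1. Slc30a1, a zinc exporter gene that responds to zinc, rose from 30.3 ± 0.32 to 404 ± 14 CPM (3.74, SE 0.081), while the metallothionein genes, which also respond to zinc, did not move with it: Mt1 had a log2 fold change of 0.06 (SE 0.085) and Mt2 fell by 0.75 (SE 0.11).

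Among 189 families of genes that share the letters of their symbol, with at least 8 tested members each, 2 were called. All 12 tested Gbp genes, interferon-induced GTPases of defence against intracellular microbes, were lower, with a median of -2.20 (limma's camera, adjusted p = 9.5e-05, and adjusted p = 0.985 with an estimated correlation). The Ccl chemokines had 9 lower and 1 higher of 14 (limma's camera, adjusted p = 0.0173, and adjusted p = 0.985 with an estimated correlation). Both families overlap lists already called, so they are not separate findings. The chemokine list holds Ccl genes, and the interferon list holds Gbp2, Gbp3, Gbp5 and Gbp7. Outside any list, the cyclin gene Ccnd2 fell from 255 ± 30 to 5.44 ± 0.12 CPM (-5.55, SE 0.13) and Slfn1 from 302 ± 1.6 to 15.2 ± 0.73 CPM (-4.31, SE 0.089).

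The fall of cytokine and chemokine transcripts (44 genes, median log2 fold change -2.06) was weighed against technical sources. A few genes taking more of the counts would move all others by 1 common factor, but under total-count scaling with no composition factor the median of all tested genes was -0.054 and that of this list -2.10. A gene length and GC correction left 0.9496 of the median. The macrophage markers had a median of 0.17 (SD 1.18 over 10 genes, 2 of them below -1), which argues against a fall in the macrophage share of the RNA by the same factor. Of these markers, 4 were higher and 4 lower, so their median is a rough measure of that share. CPM values are shares of the counts, so a loss of cells in a culture made up almost wholly of macrophages would not show in them. With these tests, the fall may be a response to MB-3 under LPS; an action on another target than GCN5 and a toxic effect stay open as untested.

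The rise of NRF2 targets (30 genes, median 1.88) was weighed in the same way. Under total-count scaling the median of all tested genes was -0.054 and that of this list 1.84, and the length and GC correction changed it by a factor of 1.06. The summed rise of the list in TMM-scaled CPM corresponds to about 5.97% of the counts. RNA of other cells would have to make up at least about that share and bring its own markers. Medians with MB-3 were taken over all fixed markers, tested or not, of each of 7 lists for cell types other than macrophages. The highest was 1.40 CPM under total-count scaling (mesothelial cells and fibroblasts). This argues against a type that supplies most markers of its list, although single markers such as Il7r (640 CPM, same scaling) were higher. Some lists pool types, such as eosinophils with mast cells and platelets with red cells. A type with the smaller part of a list could not raise its median, so nothing follows for such a type. Within the NRF2 system, the transcript of NRF2 itself (Nfe2l2) rose by 0.88, those of Mafg and of the repressor Bach1 by 1.72 and 1.91, and Keap1 fell by 0.38. The rise may be a response to loss of acetyltransferase activity or to another action of MB-3, which a single compound at a single dose does not separate.

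A further hypothesis was that the fall selects unstable messengers with AU-rich elements. Over all tested genes it was not borne out: 492 genes with at least 2 copies of the motif TTATTTAWW in the 3' UTR had a median log2 fold change 0.037 above that of 9074 genes with none, inside the central 95% of 10000 permutations within strata of expression and 3' UTR length (-0.0185 to 0.105, permutation p = 0.711, two-sided). In a simulation, a shift of -0.2 was detected by this test. Within the fixed lists the difference was -0.096 (40 genes with the motif, 45% of them lower, and 476 without, 34% lower; central 95% -0.376 to 0.274, permutation p = 0.697), too wide a spread to decide the question there. Of the 6 largest falls, Csf2 had 5 copies, Il12a and Cish 2 each, and Edn1, Il1b and Socs3 0. The data therefore suggest that this motif does not set the response across all genes, while a part in the fall of cytokine genes stays open, and longer or other decay elements were not searched.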
